A study of Mus musculus with 16 samples.

How the data were processed

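Total RNA from mouse hearts was hybridised to 8 2-colour locked nucleic acid microRNA arrays, each holding 2 samples of the same group, one labelled with the dye Hy3 and the other with Hy5. Each array held 11204 features for 2668 distinct probes, and each of the 1023 mouse probes was spotted 4 times. The authors deposited the scanner output of each array, which is an intensity per spot and channel made with Agilent Feature Extraction 9.5.3.1, per the file headers. These intensities are the mean pixel brightness of a spot and the median of its local background, with no subtraction made. The deposited files also hold a processed intensity per channel, background-adjusted and dye-normalized by the authors' extraction run per the file headers, and further columns with other spot marks of 0 or 1 for outlier, saturated and well-above-background spots. A deposited value table on the log2 scale covers the same 16 samples. How it was made is not given in the sources used here. Its columns share a median of 3.76, and each column correlated at 0.981 to 0.998 with the log2 processed intensity of its own channel and at 0.859 to 0.957 with the other channel of the same array, across 2667 probes. Its direction and log scale were read from that comparison, and its centring stays unknown.

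Analysis began from the unsubtracted intensities with R 4.3.3, limma 3.58.1 and the package data.table, version 1.17.8. Background was corrected with normexp and an offset of 50. Dye effects were removed within each array by loess, with control spots at weight 0. The distribution of spot brightness, averaged over both channels, was then set equal between arrays by the Aquantile method. Each channel was taken as one sample on the log2 scale. Spots marked as non-uniform or population outliers were left out, which removed 1.69% to 5.52% of spots per sample, and the remaining spots of a probe were averaged. Saturated spots were kept. The 1023 probes that name a mouse microRNA were tested, with 23 sample values missing over 7 of them, all 7 bright probes whose spots had been marked as outliers. Where a probe names more than 1 microRNA, both names are given. Names are those of the array design, and a star marks the less abundant strand of a precursor. No genome positions are held in the files, so none are given. The table that pairs gene symbols with reference identifiers was not used here.

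The planned filter on dim probes used the scanner's well-above-background mark, which was set for at least 99.9% of spots in every sample, so it removed no probe. Background was therefore measured with 143 probes for human viruses, and a mouse probe was taken as above background in a sample where it exceeded their 95th percentile. By that measure 208 mouse probes were above background in at least 4 of the 16 samples and 98 in all samples. This second filter was added after the data were examined.

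Groups came from the sample labels. A linear model with a mean per group and a dye term was fitted over all 16 samples with lmFit, with the array as a random block through duplicateCorrelation (consensus correlation 0.246) and moderated by eBayes. The array block has a correlation of 0.646 over the 208 probes above background. The fit left a median of 11 residual degrees of freedom per probe, and the moderation added 2.90 prior degrees of freedom. The 7 contrasts read from it were each exposed group against control, the mean of the exposed groups against control, and the 3 differences between exposed groups. P values from limma were adjusted by Benjamini-Hochberg over the tested probes, and a probe was called at an adjusted p under 0.05. The limma p values stand behind every adjusted p given for a single probe. The number of arrays limits the precision, since each group lies on 2 arrays. The median standard error of a difference from control was 0.06 on the log2 scale over all probes, and 0.09 over the probes above background.

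Lists of microRNAs were tested with camera on data from which the array correlation had been removed, with a preset inter-gene correlation of 0.01, and adjusted over the 18 lists of a comparison. A list needed at least 3 tested probes. The tests were repeated with an estimated correlation and with fry, which asks whether the members move one way on balance and makes no comparison with other microRNAs. The lists were heart and skeletal muscle, remodelling and fibrosis, the miR-29, miR-30, let-7 and miR-15/16 families, miR-17-92 and paralogous clusters, the miR-23/27/24 clusters, metabolic, glucocorticoid and stress axis, the Dlk1-Dio3 cluster, endothelial, smooth muscle, erythroid, leukocyte and inflammation, neuron, liver, and epithelial. A further set of small reference RNAs was used only to look at the scaling. Some microRNAs stand on 2 lists, such as miR-195 and miR-23b.

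The microRNAs named in the text follow a rule. For each comparison with control these are the 10 called probes with the largest rise and the 10 with the largest fall that moved the same way in all 4 exposed samples, filled up to 20 by the lowest unadjusted p. For the other comparisons they are the 5 lowest p values. To these were added 15 names of heart, fibrosis, vessel and blood microRNAs in every comparison. Of these 15 names 1 had no matching probe, the guide strand of miR-1, and because miR-208a has a probe for each strand 15 probes were tested. In all 60 probes fall under the rule. Members of the fixed lists are named as examples, and any other microRNA named was chosen after its values were seen.

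The design, the contrasts, the lists, the naming rule and most alternatives were fixed before the data were examined. The alternatives chosen in advance were other background corrections (processed intensities, no subtraction, or normexp with no offset), other scalings (median scaling between arrays, quantile normalization of single channels, or loess with no step between arrays), the deposited values, other probe sets, the median over spots, no dye term, no array block, averaged arrays, the replicate number, scan order or the slide run as a block, and leaving out each sample. The virus-probe filter, the array correlation of the probes above background set for all mouse probes, keeping the spots marked as outliers, leaving out each array and fits within a slide run were added after the data were examined. Slide numbers fall into 2 runs, separated by a gap of 166 where the next largest gap is 4. Control and T3R1 arrays make up run 1, and T1R1 and T2R1 arrays make up run 2.

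The procedure was tested on simulated data for T1R1 against control over 1016 probes, with 200 of them changed. It recovered 66 of 67 probes changed by 0.5 on the log2 scale (98.5%), 66 of 67 changed by 1 and 66 of 66 changed by 2, with 7 calls among the unchanged probes. With no change simulated, T3R1 against control gave 0 calls. A shift of 0.5 put into the miR-30 family was found by camera, with no other list called. The simulated probes varied independently of one another, with an array correlation of 0.244 and no slide-run difference. In the data the miR-30 family has an estimated inter-gene correlation of 0.31, and the probes above background an array correlation of 0.646. The recovery therefore does not cover those conditions.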

Results

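MicroRNA was measured in heart tissue of C57BL/6 mice, an inbred laboratory strain, in a mouse model of post-traumatic stress disorder. Mice were held in wire mesh boxes inside the cage of an aggressor mouse for 6 hours a day. The 3 exposed groups had 1 day (T1R1), 2 days (T2R1) or 3 days (T3R1) of exposure, each followed by 1 day of rest. Control mice were held in the same kind of box in a large cage that had no aggressor. The control titles carry the code C2R1, which the labels do not spell out. Whether controls followed the schedule of T2R1 alone is therefore not known, and T1R1 and T3R1 may differ from control in schedule as well. Each of the 4 groups held 4 samples, 16 in all. The labels' extraction protocol names individual hearts as the source of the RNA, so the replicates of a group are taken as separate hearts. The protocol text in the labels gives longer exposures than the design text does, and the number of days used here is that of the design text and the group codes. The question the design poses is how heart microRNAs vary with the length of exposure when the rest is the same.

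The median raw signal of the mouse probes lay between 41.1 and 73.3 per sample. Between 121 mouse probes (control replicate 1) and 237 (T1R1 replicate 4) were above the level of probes for human viruses. That number was 172 ± 37.1 in control (SD, n = 4), 197 ± 33.7 in T1R1, 186 ± 7.14 in T2R1 and 174 ± 22.5 in T3R1. None of the 3 differences from control was larger than the spread between samples (2-sided exact permutation p of 0.371, 0.657 and 0.971 over 70 regroupings). The regroupings take single samples as exchangeable and ignore dye and array. The number was higher in Hy5 than in Hy3 on every array but that of T2R1 replicates 3 and 4 (188 in Hy3 and 185 in Hy5). The spread therefore holds a dye difference and is not that between hearts alone. Across 201 probes above background, samples of a group correlated at 0.937 to 0.985, and all samples at 0.911 to 0.990.

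The arrays came from 2 runs of slide numbers, with control and T3R1 in run 1 and T1R1 and T2R1 in run 2. Landing lights, pre-labelled positioning spots that bind none of the sample's RNA, were brighter in run 2, at 27715 ± 1912 (SD, n = 4 arrays) against 18106 ± 574 in run 1. The ratio was 1.53, and the 2-sided exact permutation p of 0.0286 is the smallest that the 70 regroupings of 8 arrays can give. In every comparison of T1R1 or T2R1 with control or T3R1, slide run and group therefore cannot be told apart. T3R1 against control and T2R1 against T1R1 lie within a run.

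**Figure D1:**
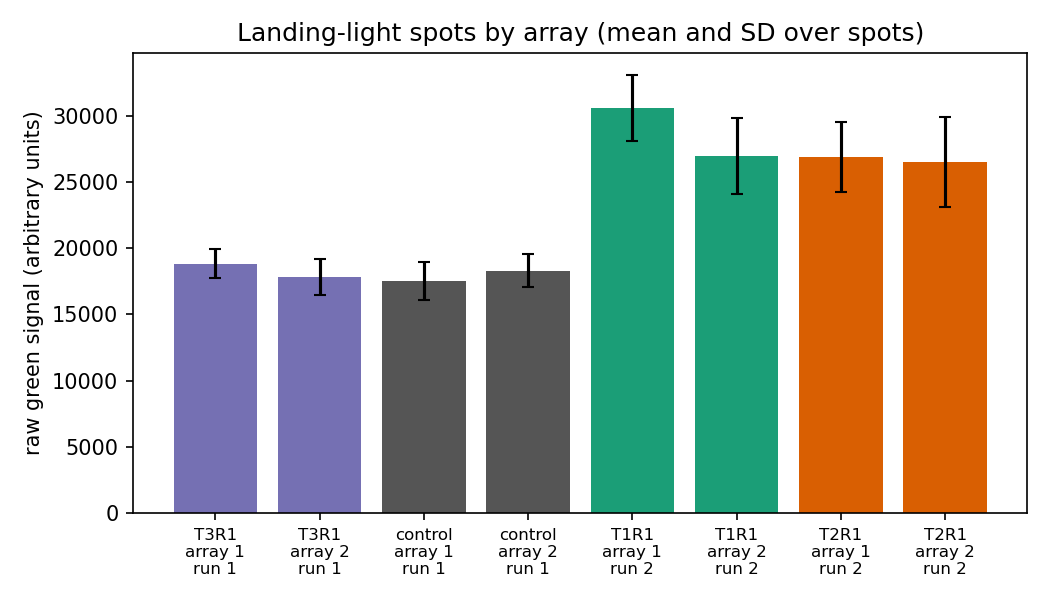
Raw green-channel signal of landing-light spots in arbitrary units, 1 bar per array (mean, with the SD over its spots), coloured by group. The 4 arrays of run 1 lie between 17492 and 18812 and the 4 arrays of run 2 between 26473 and 30566.

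After 1 day of exposure the signals of miR-30a and let-7a were higher than in control. Slide run and exposure cannot be told apart in this comparison, and both calls were lost with the 2 samples of an array averaged. miR-30a, from a family abundant in heart muscle, rose 1.60-fold, by 0.68 ± 0.07 on the log2 scale (SE, n = 4 against 4), from 7.75 ± 0.11 (SD) in control to 8.43 ± 0.11. let-7a, from a family of regulators of growth and differentiation, rose 1.43-fold, by 0.51 ± 0.07, from 7.61 ± 0.05 to 8.12 ± 0.04. The limma adjusted p was 0.000204 for miR-30a and 0.00118 for let-7a, and all 4 exposed samples lay above the control mean for both. The star strand of miR-133a, a microRNA enriched in muscle, rose by 0.43 ± 0.07 (limma adjusted p = 0.00742). miR-582-3p, miR-1186b and miR-467a* were lower, with log2 differences of -0.46 ± 0.08, -0.56 ± 0.11 and -0.31 ± 0.07.

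Of 1021 probes tested, 12 were called in T1R1, 9 higher and 3 lower, and all 12 moved the same way in 4 of 4 samples. The other 6 called higher were miR-24-1* (0.31), miR-149 (0.23), miR-883a-5p (0.41), miR-503* (0.34), miR-690 (0.70) and miR-720 (0.90), with limma adjusted p values from 0.0129 to 0.0446. miR-720, a name given to what was later traced to a fragment of transfer RNA, had a usable value in 1 of the 4 control samples, so its call rests on that sample and the fitted dye term. At an unadjusted p under 0.05 there were 88 probes, where 51.1 are expected by chance. The next lowest p values, none of them called, belonged to miR-23b (0.55 ± 0.13), miR-181a (0.22 ± 0.05), miR-150 (-0.18 ± 0.04), miR-30e* (0.29 ± 0.07), miR-3473 (0.42 ± 0.11), miR-30d (0.25 ± 0.06), miR-138-2* (-0.15 ± 0.04) and miR-743a (0.32 ± 0.08).

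Among the groups of microRNAs, the miR-30 family was higher in T1R1. Of its 5 members 4 had positive differences and 1 negative, 1 was called, and 2 (miR-30a and miR-30d) passed when adjusted over the list alone. Its camera adjusted p was 0.0252. The call was lost with an estimated correlation (adjusted p = 0.631 with an estimated correlation) and with fry (fry adjusted p = 0.108). The remodelling and fibrosis list was also higher, with 11 of 13 members positive, 0 called, and 3 passing when adjusted over the list alone, namely miR-23b, miR-34a and miR-199a-5p. miR-34a is known for its link to cardiac ageing. miR-21, the list's best known marker of cardiac fibrosis, had a difference of -0.16 ± 0.19. The adjusted p of that list was 0.0318 by camera, 0.631 with an estimated correlation and 0.418 by fry. In the let-7 family 4 of 8 members were positive and 1 was called, with 1 passing when adjusted over the list alone, and the median difference of -0.01 and the mean of 0.05 differ in sign. Of the 7 heart and skeletal muscle members 4 were positive, 3 negative and 0 called, with 0 passing when adjusted over the list alone: miR-133a stood at 0.38 ± 0.18, miR-499 at 0.00 ± 0.11 and miR-208a-3p at -0.37 ± 0.24 from control, the last 2 turning positive under median scaling. miR-208a-3p has values in 3 of 4 control samples, and without control replicate 1 its difference was 0.03 ± 0.17.

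The other 14 lists were not called in T1R1, with camera adjusted p values from 0.0616 for miR-17-92 and paralogous clusters (13 of 14 members positive) to 0.941 for the Dlk1-Dio3 cluster (32 of 51 positive). Markers of other cell types were among them. The erythroid list had 4 of 4 members positive, the endothelial list 4 of 4, the smooth muscle list 2 of 3 and the leukocyte and inflammation list 5 of 9, of which miR-150, typical of mature lymphocytes, passed when adjusted over the list alone (1 member). Of the remaining lists, the miR-29 family had 3 of 3 members positive, the miR-15/16 family 3 of 6, the miR-23/27/24 clusters 3 of 5, metabolic 6 of 7, glucocorticoid and stress axis 3 of 6, neuron 3 of 8, liver 3 of 3 and epithelial 2 of 10. Slide run and group cannot be told apart here, and median scaling between arrays called 202 probes, 196 higher and 6 lower, in place of 9 and 3, with miR-582-3p, miR-1186b and miR-467a* at positive differences, miR-30a at 1.30 in place of 0.68, and miR-149 negative under loess with no step between arrays. That last setting went the other way and called 607 probes, 7 higher and 600 lower. With the array correlation of the probes above background set for all probes 4 were called, miR-30a, let-7a, miR-720 and miR-582-3p. With the 2 samples of an array averaged 0 were called, with limma adjusted p values of 0.0566 for miR-30a and let-7a. Normexp with offset 0 and the deposited values called 1 probe each, and quantile normalization 2. let-7a, miR-133a* and miR-582-3p lost their calls under normexp with offset 0, loess with no step between arrays and the deposited values. Left-out samples that moved the count of 12 by over 1.5 times were control replicate 1 (20 without it) and T1R1 replicates 2 and 4 (6 without either), while miR-30a, let-7a, miR-133a* and miR-582-3p were called with each of the 16 samples left out. The call was kept in 3 of these 16 fits for miR-503*, 5 for miR-690, 7 for miR-467a*, 9 for miR-883a-5p, 12 for miR-1186b and 13 each for miR-24-1* and miR-149.

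After 2 days of exposure let-7a and miR-30a were again higher than in control, in a comparison that also lies across the slide runs. let-7a rose 1.71-fold, by 0.77 ± 0.07 on the log2 scale (SE, n = 4 against 4), to 8.38 ± 0.07 (SD), and miR-30a rose 1.65-fold, by 0.72 ± 0.07, to 8.47 ± 0.06. The limma adjusted p was 1.8e-05 for let-7a and 4.9e-05 for miR-30a, with 4 of 4 samples above the control mean. The star strands miR-24-1* and miR-133a* rose by 0.42 ± 0.06 and 0.42 ± 0.07. miR-150, typical of mature lymphocytes, was lower in 4 of 4 samples, with a log2 difference of -0.25 ± 0.04 (limma adjusted p = 0.00635).

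Of 1022 probes tested, 12 were called in T2R1, 9 higher and 3 lower. Besides the 4 that rose above, miR-883a-5p (0.51), miR-677* (0.61), miR-690 (0.70), miR-883b-5p (0.29) and miR-720 (1.09, against 1 control sample with a usable value) were called higher, with limma adjusted p values from 0.00287 to 0.0498. miR-883b-5p was not above the virus-probe level in any T2R1 or control sample. miR-582-3p (-0.41 ± 0.08) and miR-1186b (-0.53 ± 0.11) were lower, as in T1R1. At an unadjusted p under 0.05 there were 81 probes, where 51.1 are expected by chance. The lowest p values that were not called belonged to miR-691 (0.58 ± 0.13), miR-138-2* (-0.16 ± 0.04), miR-7a-2* (0.44 ± 0.11), miR-3473 (0.43 ± 0.11), miR-301b* (0.27 ± 0.07), miR-34b-3p (0.37 ± 0.10), miR-149 (0.16 ± 0.04) and miR-665* (0.27 ± 0.08).

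**Figure D2:**
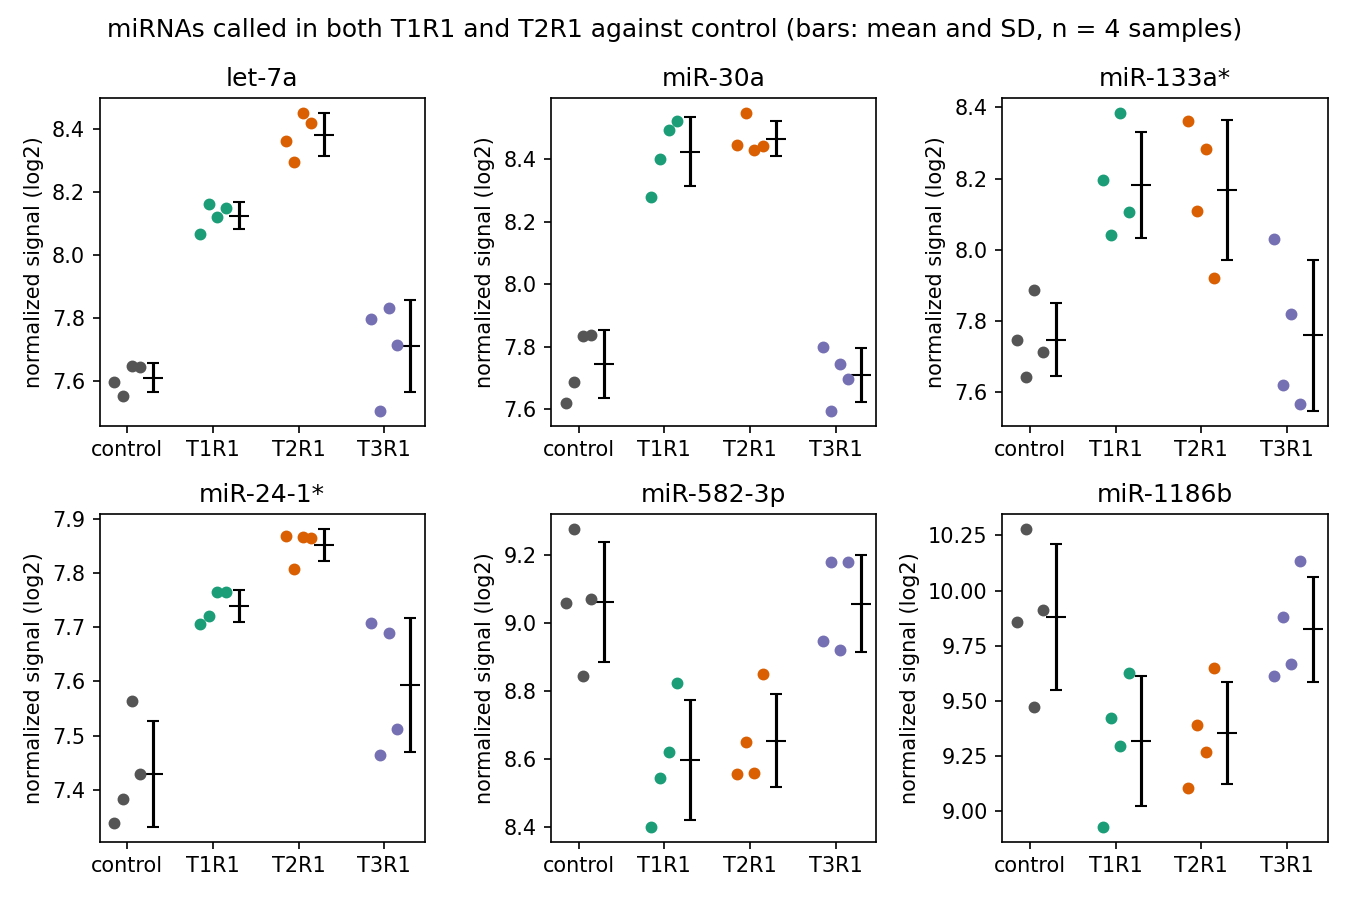
Normalized log2 signal of 6 of the 9 microRNAs called in both T1R1 and T2R1 against control, 1 panel each with its own axis, which does not start at 0. Points are samples and bars the mean and SD of 4 samples. For let-7a the group means are 7.61 in control, 8.12 in T1R1, 8.38 in T2R1 and 7.71 in T3R1.

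The miR-30 family was higher in T2R1, with 5 of 5 members positive, 1 called and 2 (miR-30a and miR-30d) passing when adjusted over the list alone. Its camera adjusted p was 0.00714. The call was lost with an estimated correlation (adjusted p = 0.422 with an estimated correlation) and with fry (fry adjusted p = 0.117). The other 17 lists were not called, with camera adjusted p values from 0.118 for the epithelial list (2 of 10 members positive, none above background in 4 samples) to 0.976. In the let-7 family 4 of 9 members were positive, 1 was called and 1 passed when adjusted over the list alone, and the median of -0.01 and the mean of 0.04 differ in sign. The heart and skeletal muscle list had 5 of 7 members positive and 0 called, with miR-133a at 0.15 ± 0.18 and miR-208a-3p at -0.42 ± 0.24, or -0.02 ± 0.17 without control replicate 1. In the leukocyte and inflammation list 5 of 9 members were negative and 1 was called, miR-150, which alone passed when adjusted over the list alone. The erythroid list had 4 of 4 positive members and 0 called. Slide run and group cannot be told apart here either, and median scaling between arrays called 183 probes, 179 higher and 4 lower, with miR-582-3p, miR-1186b and miR-150 at positive differences, miR-30a at 1.32 in place of 0.72, and miR-883b-5p negative under loess with no step between arrays. That last setting went the other way and called 661 probes, 6 higher and 655 lower. Processed signals called 2 and normexp with offset 0 called 3. let-7a and miR-30a in T2R1 were called under all 43 other settings in which they could be tested. With the array correlation of the probes above background set for all probes they and miR-720 were the only 3 calls. With the 2 samples of an array averaged they were the only 2 calls, and the other 10 were lost. With each of the 16 samples left out in turn, the call was kept in 2 fits for miR-883b-5p, 6 for miR-690, 7 for miR-1186b and 11 for miR-677*.

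In all, 9 microRNAs were called in the same direction in T1R1 and T2R1, namely let-7a, miR-30a, miR-133a*, miR-24-1*, miR-883a-5p, miR-690 and miR-720 (higher) and miR-582-3p and miR-1186b (lower). The comparisons share their control samples, and for miR-720 both rest on the same single control value. In 100 simulations of unchanged groups against the same controls the mean overlap was 0 and the highest 0, and lists of these sizes drawn independently would share 0.0881. An unchanged group gave 0 calls in the test on simulated data, so a simulated overlap of 0 was near certain in advance. The simulations also hold no slide-run difference, which T1R1 and T2R1 share against control, so they exclude nothing about it. With a different control array for each comparison, 4 microRNAs were shared in each of the 2 ways of dividing the controls (12 and 24 calls in the first, 26 and 10 in the second). The overlap of 9 was 0 with the 2 samples of an array averaged, 3 with the array correlation of the probes above background, 1 with normexp at offset 0 and with the deposited values, 2 with processed signals and with quantile normalization, 155 under median scaling, 594 under loess with no step between arrays, and 5 without T1R1 replicate 2. T2R1 and T1R1 differed in no probe of 1022, with 37 at an unadjusted p under 0.05 against 51.1 expected by chance and a smallest limma adjusted p of 0.999. let-7a, with the lowest p values, stood 0.26 ± 0.07 higher in T2R1, and miR-340-5p at -0.13 ± 0.04, miR-3084* at -0.21 ± 0.06, miR-487b at 0.18 ± 0.06 and miR-93 at -0.20 ± 0.07 were next. A fit on the 8 samples of run 2 alone gave 0 calls too.

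Between T2R1 and T1R1, 3 lists were lower in T2R1 by camera: miR-17-92 and paralogous clusters (12 of 14 members negative, adjusted p = 0.0437), leukocyte and inflammation (8 of 9 negative, 0.0437) and the miR-23/27/24 clusters (4 of 5 negative, 0.0462). None had a called member, and 0 members passed when adjusted over the list alone. All 3 calls were lost with an estimated correlation (adjusted p = 0.613 for each with an estimated correlation) and with fry (fry adjusted p = 0.784 for each).

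After 3 days of exposure no microRNA passed the test against control. let-7a and miR-30a stood at 0.10 ± 0.07 and -0.04 ± 0.07 from control on the log2 scale (SE, n = 4 against 4). The lowest p values belonged to miR-493* (0.49 ± 0.10), miR-767 (0.36 ± 0.09), miR-214 (0.33 ± 0.08) and miR-146a (-0.22 ± 0.05), a regulator of innate immune signalling, each in 4 of 4 samples and each with a limma adjusted p of 0.302. miR-208a-3p, encoded within the gene of a cardiac myosin heavy chain, stood at -0.85 ± 0.24 (limma adjusted p = 0.469) with values in 3 of 4 control samples, or at -0.45 ± 0.17 without control replicate 1, and miR-499, likewise encoded within a myosin gene, at -0.38 ± 0.11 (0.488).

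Of 1022 probes tested by limma in T3R1, 0 were called, 70 had an unadjusted p under 0.05, and 51.1 are expected by chance. Others among the lowest p values were miR-669e* (0.27 ± 0.07), miR-448-5p (-0.24 ± 0.07), miR-16 (-0.40 ± 0.12), miR-143* (-0.16 ± 0.05), miR-15a (-0.30 ± 0.10), let-7i (-0.32 ± 0.11), miR-21* (0.34 ± 0.11), miR-214* (0.18 ± 0.06), miR-152* (-0.14 ± 0.05) and miR-1196 (0.25 ± 0.08). miR-21 stood at 0.52 ± 0.19, the endothelial miR-126-3p at -0.43 ± 0.19, and the erythroid miR-451 at -0.97 ± 0.52, with values in 2 of 4 samples of each group.

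By list, 3 groups were lower in T3R1 than in control. The leukocyte and inflammation list had 9 of 9 members negative, the miR-30 family 5 of 5 and the miR-15/16 family 5 of 6, with 0 called members in each. When adjusted over the list alone, 1 leukocyte member (miR-146a), 0 of the miR-30 family and 2 of the miR-15/16 family (miR-16 and miR-15a) passed. The camera adjusted p values were 0.00045, 0.0128 and 0.0175. All 3 calls were lost with an estimated correlation (adjusted p = 0.242, 0.31 and 0.31 with an estimated correlation). They were also lost with fry (fry adjusted p = 0.162, 0.268 and 0.268). Members lay further below control on 1 of the 2 T3R1 arrays, with medians from control of -0.14 on array 1 and -0.40 on array 2 for the miR-30 family, -0.08 and -0.37 for the miR-15/16 family and -0.08 and -0.13 for the leukocyte list. Without array 2 the calls of the 2 families were lost (camera adjusted p = 0.26 and 0.355), as they were without control array 2 (0.105 and 0.0866), and all 3 were lost without control array 1 (0.0559, 0.256 and 0.256). Of the 9 leukocyte members 5 were above background in at least 4 samples. Camera's direction, which is relative to the other tested probes, turned to higher for these 3 lists under loess with no step between arrays. For the 2 families it also turned under median scaling. Under loess with no step the probes as a whole lay below control, so a list that turned stood higher than the other probes. It need not have stood higher than control.

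The other 15 lists were not called in T3R1, with camera adjusted p values from 0.0836 to 0.873. The heart and skeletal muscle list had 6 of 7 negative members, of which 2 (miR-499 and miR-208a-3p) passed when adjusted over the list alone, at a camera adjusted p of 0.124. Of other cell types, smooth muscle had 3 of 3 members negative, with miR-143* passing when adjusted over the list alone (1 member), at a camera adjusted p of 0.0836, which miR-17-92 and metabolic share, and endothelial 3 of 4. The miR-29 family had 3 of 3 negative (0.104) and the erythroid list 4 of 4 negative, with a median of -0.21 (0.321). By camera these lists, like the muscle list, turned to higher than the other probes under loess with no step between arrays. Of the remodelling and fibrosis members 6 of 13 were positive, with miR-214 passing when adjusted over the list alone (1 member), and median and mean of -0.01 and 0.05 differ in sign. A fit on the 8 samples of run 1 alone gave 0 calls, and so did the slide run as a block. The count of 0 was 30 (30 higher, 0 lower) under median scaling, 702 (0 higher, 702 lower) under loess with no step between arrays, and 2 over all non-control probes. It also rose without control array 1 (19 called), control array 2 (9), T3R1 array 1 (8) or T3R1 array 2 (1), and to 1 without control replicate 2, without T3R1 replicate 1 or with scan order (the first or last 4 arrays scanned) as a block.

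**Figure D3:**
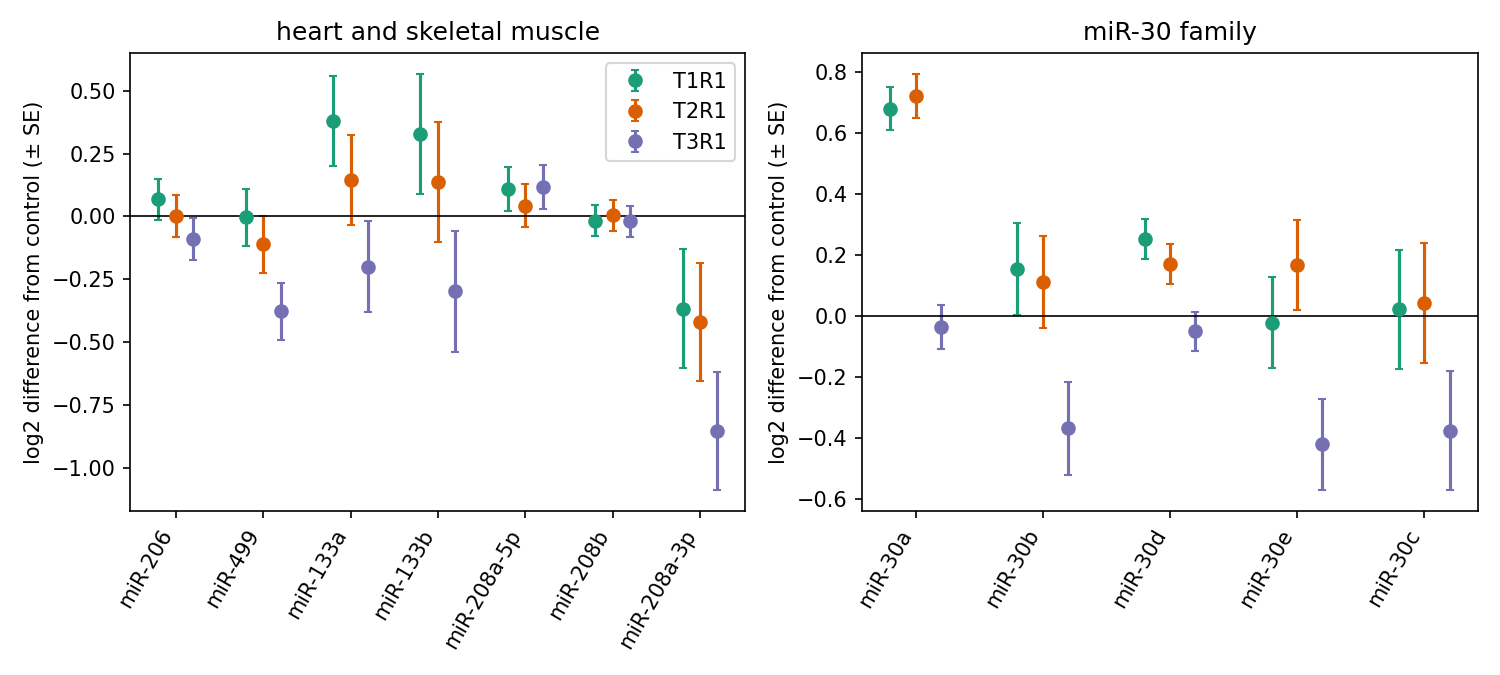
Log2 difference from control with its standard error for the members of the heart and skeletal muscle list (left) and of the miR-30 family (right), in T1R1, T2R1 and T3R1. miR-30a stands at 0.68 and 0.72 in T1R1 and T2R1 and at -0.04 in T3R1. The 5 family members are all below 0 in T3R1. Camera sets the family against the other probes, and its direction turned under median scaling and under loess with no step between arrays.

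T3R1 was also compared with T1R1 and T2R1. T3R1 lies in run 1 and T1R1 and T2R1 in run 2, so slide run and exposure length cannot be told apart in these tests. miR-30a was lower in T3R1 than in T1R1 or T2R1, at -0.72 ± 0.07 from T1R1 and -0.76 ± 0.07 from T2R1 (limma adjusted p = 0.000109 and 5.1e-05). let-7a was lower by the same test, at -0.41 ± 0.07 and -0.67 ± 0.07 (limma adjusted p = 0.00327 and 5.1e-05). miR-133a* stood at -0.42 ± 0.07 and -0.41 ± 0.07 and miR-720 at -0.86 ± 0.10 and -1.05 ± 0.10, and both passed in each comparison. miR-138-2* was higher in T3R1, by 0.26 ± 0.04 and 0.28 ± 0.04, as were miR-582-3p, by 0.46 ± 0.08 and 0.40 ± 0.08, and miR-467a*, by 0.41 ± 0.07 and 0.31 ± 0.07. miR-30e* (-0.52 and -0.35) and miR-149 (-0.30 and -0.23) were lower in both.

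T3R1 against T1R1 gave 26 calls among 1022 probes, 9 higher and 17 lower, and T3R1 against T2R1 gave 10 among 1023, 4 higher and 6 lower. The miR-30 family was lower in both, with 5 of 5 members negative each time. Against T1R1 2 members were called, 4 passed when adjusted over the list alone, and the camera adjusted p was 1.4e-05 (adjusted p = 0.108 with an estimated correlation). Against T2R1 1 was called, 5 passed when adjusted over the list alone, and the camera adjusted p was 2.3e-07 (adjusted p = 0.0433 with an estimated correlation). Of all 16 list calls this last one alone held with an estimated correlation. The family's median was -0.27 on T3R1 array 1 and -0.57 on array 2 from T1R1, and -0.42 and -0.65 from T2R1, and both calls held without array 2 (camera adjusted p = 0.00123 and 0.000109). The 14 brightest mouse microRNAs with complete values also lay lower in T3R1. Their median from control was 0.20 in T1R1, 0.08 in T2R1 and -0.29 in T3R1. The family was not tested against microRNAs of like brightness.

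Against T1R1 5 further lists were lower in T3R1: miR-17-92 and paralogous clusters (13 of 14 members negative, camera adjusted p = 0.00136), leukocyte and inflammation (8 of 9, 0.00895), metabolic (7 of 7, 0.013), the miR-15/16 family (6 of 6, 0.0291) and heart and skeletal muscle (6 of 7, 0.0374). When adjusted over the list alone 1, 1, 1, 0 and 3 of their members passed, among them miR-146a and, of the muscle list, miR-499, miR-133a and miR-133b. Markers of other cell types lay lower too, though their lists were not called. The erythroid list had 4 of 4 members negative against T1R1 (median -0.41, miR-3107/miR-486 passing when adjusted over the list alone) and against T2R1 (median -0.46), and the endothelial list 4 of 4 (miR-126-5p and miR-126-3p passing) and 3 of 4. Without T3R1 array 2 all 5 calls were lost (camera adjusted p from 0.129 to 0.44). With an estimated correlation these calls were lost (adjusted p = 0.238 for miR-17-92 and 0.236 for the others with an estimated correlation). All calls of T3R1 against T1R1 and T2R1 lie across the slide runs, so slide run and group cannot be told apart, and the difference of miR-138-2* from T1R1 was negative under median scaling and under loess with no step between arrays. Under loess with no step between arrays 0 and 1 were called, with miR-30a lost in both comparisons and let-7a against T2R1. Processed signals gave 5 and 4, normexp with offset 0 gave 4 and 4, quantile normalization 5 and 4, the deposited values 3 and 4, and median scaling 84 (2 higher, 82 lower) and 32 (1 higher, 31 lower). With the 2 samples of an array averaged 2 calls remained in each comparison, and with the array correlation of the probes above background 7 against T1R1 and 3 against T2R1. The count of 26 against T1R1 was 10 without T3R1 replicate 3 or 4 or T1R1 replicate 4, 12 to 17 without control replicate 2, T3R1 replicate 2, T1R1 replicate 2 or 3, or T2R1 replicate 1 or 3, and that of 10 against T2R1 was 19 without control replicate 1 and 6 without control replicate 2, T3R1 replicate 3 or 4, or T2R1 replicate 1, 2 or 3.

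For the mean of the 3 exposed groups against control, 8 of 1021 probes were called, 6 higher and 2 lower, with 83 at an unadjusted p under 0.05. let-7a rose by 0.46 ± 0.05 and miR-30a by 0.46 ± 0.06 on the log2 scale (limma adjusted p = 0.000781 and 0.00106). miR-883a-5p (0.41), miR-24-1* (0.30) and miR-133a* (0.29) also rose, and miR-720 (0.68) was called against 1 control value. miR-150 (-0.18 ± 0.03) and miR-582-3p (-0.29 ± 0.06) were lower. No list was called, the smallest camera adjusted p being 0.129, for the remodelling and fibrosis list (11 of 13 members positive) and the epithelial list (2 of 10). Under median scaling 213 were called, 204 higher and 9 lower, and the difference of miR-150 was positive. Loess with no step between arrays called 768, 2 higher and 766 lower, with the calls of let-7a and miR-30a lost. The control samples lie in run 1 with T3R1 alone, so 2 of the 3 exposed groups differ from control in slide run as well. With the 2 samples of an array averaged 0 were called, and with the array correlation of the probes above background 2. The count was 4 without T3R1 replicate 2 or T2R1 replicate 3, and 5 without T3R1 replicate 3 or 4 or T2R1 replicate 1 or 2.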

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

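The tests of slide run, array correlation, exposure length, bright spike-ins, single arrays and blood in this part, and the counts over groupings of whole arrays, were chosen only after the result was seen, and the counts over other groupings of single samples were planned.

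Under a test for a sample that stands apart from the other 3 of its group, 5 of 236 groups of named microRNAs passed, where chance gives about 1 in 20, or 11.8. They were miR-30a at 8.55 in T2R1 replicate 2 (the others at 8.43 to 8.44), miR-24-1* at 7.81 in T2R1 replicate 2 (7.87 in the others), miR-3473 at 7.79 in T1R1 replicate 1 (7.44 to 7.50), miR-142-3p at 7.02 in control replicate 4 (7.40 to 7.46) and miR-16 at 9.60 in T2R1 replicate 4 (9.43 to 9.44).

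Differences from control that were themselves unequal between exposed groups, by limma's test of that difference, made up the next kind. All of them lie across the slide runs, so slide run and exposure length cannot be told apart in them. T3R1 differed from T1R1 on the log2 scale for miR-720 (-0.86), miR-30a (-0.72), miR-23b (-0.65), miR-30e* (-0.52), miR-133a* (-0.42), let-7a (-0.41), miR-146a (-0.33), miR-30d (-0.30), miR-149 (-0.30), miR-181a (-0.22), miR-138-2* (0.26), miR-1196 (0.33), miR-767 (0.41), miR-467a* (0.41), miR-493* (0.45), miR-582-3p (0.46) and miR-1186b (0.51). T3R1 differed from T2R1 for miR-720 (-1.05), miR-30a (-0.76), let-7a (-0.67), miR-133a* (-0.41), miR-30e* (-0.35), miR-149 (-0.23), miR-138-2* (0.28), miR-467a* (0.31) and miR-582-3p (0.40).

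Probes outside the mouse set also gave signals that differed from control. Among 1120 probes for microRNAs of other species, 15 were called in T1R1, 15 in T2R1 and 1 in T3R1, and among 232 probes with no microRNA name 12 were called in T1R1 and 10 in T2R1. The share called in T1R1 and T2R1 was 1.34% and 1.34% for other species and 5.17% and 4.33% for unnamed probes. For mouse probes it was 1.18% and 1.17%, so mouse probes were called no more often than these 2 classes. The origin of these signals was not tested.

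A first pattern is that microRNAs were called against control in T1R1 and T2R1 and none in T3R1. Of 35 groupings of single samples only the real one gave 12 calls, in T1R1 (1 of 35, highest other 3) and in T2R1 (1 of 35, highest other 2), but the 2 samples of an array are not independent, and whole arrays allow 3 groupings (highest other 1 and 0), too few for a share under 0.05. An array correlation set too low by dim probes stays open, since with the 0.646 of the probes above background set for all mouse probes 3 of the 9 shared microRNAs were still called in both (miR-30a, let-7a and miR-720, the last against 1 usable control value in both), with 4 calls in T1R1 and 3 in T2R1, and with averaged arrays the overlap was 0. What also stays open is the slide run, whose landing lights differed by a ratio of 1.53, and an effect of 1 or 2 days of exposure that is gone after 3, since 0 slide runs hold both control samples and a group exposed for 1 or 2 days. Slide run and exposure cannot be told apart, as the groups with calls are the groups of the other run.

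A second pattern is that the 14 brightest mouse microRNAs with complete values lay lower in T3R1 than in control, with a median of -0.29 and 14 of 14 lower, though under median scaling their median stood at 0.28 above control. A loss of signal at the bright end through normalization is argued against, since spike-in probes of the same brightness had a median of 0.17 above control, and the microRNAs lay below the spike-ins in the main analysis and under each of the other scalings and background corrections, by -0.47 to -0.29. Median scaling and loess with no step between arrays give the same gap of -0.41 by design, so they are not separate checks. The test of less blood decided nothing, as 0 of the 14 are on a blood list and leaving out blood microRNAs, with the median at -0.29, removed no probe. The median was -0.10 on T3R1 array 1 and -0.52 on array 2, the split looked for if 1 of the 2 T3R1 arrays was the source. The control arrays split alike, with array 1 at 0.20 and array 2 at -0.20 from their mean. T3R1 array 1 lay below control array 1 but above control array 2, and T3R1 array 2 lay below both. Array numbers count the arrays within a group and are not known to pair T3R1 arrays with control arrays. Whether 1 array is the source therefore stays undecided. Exposure of 3 days stays open as an untested biological explanation.

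For the other counts, T3R1 against control gave 0 calls, so that 35 of 35 groupings gave as many. The grouping that follows scan order and array number alike gave 18, the highest other. It keeps arrays whole and points to a structure of these samples, and scan order and array number cannot be told apart in it. With scan order as a block 1 probe was called. T2R1 against T1R1 gave 0, again as many in 35 of 35 groupings, with 1 as the highest other. For T3R1 against T1R1 the real grouping alone gave 26 calls (1 of 35, highest other 0), and for T3R1 against T2R1 it alone gave 10 (1 of 35, highest other 8, in the grouping that follows scan order and array number alike, with 14 calls once scan order was a block). Over whole arrays each of these has 3 groupings, with the same highest others, too few for a share under 0.05. For the mean of the exposed groups 1 of 100 groupings of single samples gave 8 calls (highest other 2), but over whole arrays 16 of 100 did, the highest other at 40, so chance cannot be excluded there, and a count of 40 also points to a structure of the arrays.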

How the results depend on the processing

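Of the settings here, the virus-probe filter, the array correlation of the probes above background, keeping spots marked as outliers, leaving out arrays and fits within a run, and the tests of neighbouring probes and spike-ins, were chosen only after the result was seen. Of 7922 values for named microRNAs under other settings, 7349 kept direction and side of the threshold, 384 kept direction but were no longer called, 168 became called and 21 turned round; for the lists the numbers were 5309, 166, 195 and 23 of 5693. let-7a and miR-30a in T2R1 were called under 43 of 43 settings, and in T1R1 under 39 and 42 of 43. Counts are given in the order T1R1, T2R1 and T3R1 against control, where they moved by over 1.5 times from 12, 12 and 0, with 8 for the mean of the exposed groups, 0 for T2R1 vs T1R1, 26 for T3R1 vs T1R1, 10 for T3R1 vs T2R1, 9 for the overlap of calls and 16 for list tests. Processed signals gave 7 (3 higher and 4 lower, against 9 and 3) and 2, then 5 for T3R1 vs T1R1, 4 for T3R1 vs T2R1, an overlap of 2 and 8 lists. Normexp with offset 0 gave 1, 3, a mean-group count of 2, then 4 and 4, an overlap of 1 and 8 lists. Median scaling gave 202 (196 higher, 6 lower), 183 (179 and 4), 30 (30 and 0), a mean-group count of 213 (204 and 9), then 84 (2 and 82, against 9 and 17) and 32 (1 and 31, against 4 and 6), an overlap of 155 and 56 lists. Quantile normalization gave 2 (2 higher, 0 lower) in T1R1, 13 (13 and 0) in T2R1, a mean-group count of 5 (5 and 0), then 5 (1 and 4) and 4 (1 and 3), and an overlap of 2. Loess with no step between arrays moved the median of all probes by -0.59, -0.62 and -0.62 and gave 607 (7 higher, 600 lower), 661 (6 and 655), 702 (0 and 702), a mean-group count of 768 (2 and 766), then 0 and 1, an overlap of 594 and 60 lists; against that shift miR-30a stood at 0.68 in T1R1. The deposited values gave 1, 7, a mean-group count of 5, then 3 and 4, and an overlap of 1. All non-control probes gave 27, 32, 2, a mean-group count of 21, then 18 for T3R1 vs T2R1 and an overlap of 20, more probes being tested. The median over spots gave a mean-group count of 5, no dye term 16 for T3R1 vs T1R1, and no array block 19 in T1R1 and 16 for T3R1 vs T2R1. Arrays averaged gave 0, 2, a mean-group count of 0, then 2 and 2, an overlap of 0 and 10 lists, with fewer samples in the fit. Scan order as a block gave 1 in T3R1, and the slide run as a block could be used only within a run, so the other comparisons have no value for it. The virus-probe background filter gave 7 in T1R1, a mean-group count of 2, then 10 and 3, and 3 lists, fewer probes being tested at a higher array correlation. The array correlation of the probes above background, set for all mouse probes, gave 4 (3 higher, 1 lower), 3 (3 and 0), a mean-group count of 2 (2 and 0), then 7 (2 and 5) and 3 (0 and 3), and an overlap of 3. Lists called with an estimated correlation numbered 1, and with fry 7. Of those called with fry, 6 were for T3R1 vs T1R1 and 1 for T3R1 vs T2R1. Fry called 0 lists in each comparison with control and in T2R1 vs T1R1. Leaving out 1 sample gave 6 to 20, 8 to 17 and 0 to 1, a mean-group count of 4 to 8, 0 for T2R1 vs T1R1, 10 to 37, 6 to 19, an overlap of 5 to 11 and 9 (without control replicate 4) to 28 lists (without T3R1 replicate 1). Leaving out 1 array, which leaves a group with 2 samples, gave 5 to 45, 5 to 36 and 0 to 19, the highest each without control array 1, then a mean-group count of 5 to 40, 0 to 1, 4 to 48, 3 to 28, an overlap of 3 to 31 and 9 to 36 lists. Under median scaling these turned round: in T1R1, miR-1186b (0.53), miR-582-3p (0.46), miR-467a* (0.31), miR-138-2* (0.49), miR-499 (0.76) and miR-208a-3p (0.71); in T2R1, miR-1186b (0.55), miR-582-3p (0.50), miR-150 (0.0576), miR-138-2* (0.45), miR-29b (0.80) and miR-499 (0.63); in the mean of the 3 stressed groups vs control, miR-150 (0.0945), miR-29b (0.66), miR-29c (0.67), miR-499 (0.48) and miR-126-3p (0.72); and miR-138-2* in T3R1 vs T1R1 (-0.0338). Under loess with no step, miR-149 in T1R1 (-0.13), miR-883b-5p in T2R1 (-0.25) and miR-138-2* in T3R1 vs T1R1 (-0.0481) turned round. These turns go with shifts of all probes of that brightness: the 50 mouse probes nearest in signal moved the same way as the microRNA in 18 of 18 cases under median scaling and 3 of 3 under loess with no step, and with their median shift taken off, 15 of 18 and 3 of 3 kept the main direction. Both scalings differ from the main one only in the step between arrays. The main step sets the distribution of spot brightness equal between arrays, so probes of equal brightness shift together by design. These counts therefore do not show which direction is right. Bright spike-in probes stood at 0.99, 0.87 and 0.69 above control in T1R1, T2R1 and T3R1 under median scaling, against 0.04, -0.02 and 0.17 in the main analysis. List directions below are those of camera, relative to the other tested probes, and are not the sign of the members against control. The lists that turned from lower to higher had these adjusted p values, first under median scaling and then under loess with no step: miR-15/16 family, T2R1 vs control (0.0138 and 0.00318), miR-30 family, T3R1 vs control (0.281 and 0.0133), let-7 family, T3R1 vs control (0.00152 and 0.000117), miR-15/16 family, T3R1 vs control (0.666 and 0.253), miR-23/27/24 clusters, T3R1 vs control (0.00802 and 5.5e-05), heart and skeletal muscle, mean of the 3 stressed groups vs control (0.00623 and 0.000505), miR-29 family, mean of the 3 stressed groups vs control (0.0473 and 2.8e-05), miR-15/16 family, mean of the 3 stressed groups vs control (0.0351 and 0.00667) and metabolic, mean of the 3 stressed groups vs control (0.0352 and 0.0142). Under loess with no step alone these were heart and skeletal muscle, T3R1 vs control (0.0157), miR-29 family, T3R1 vs control (0.0133), erythroid (blood), T3R1 vs control (0.0157), leukocyte and inflammation (blood, other cell type), T3R1 vs control (0.703) and endothelial (other cell type), mean of the 3 stressed groups vs control (0.028). Where no reason is given, the cause was not tested. Deviations of same-numbered samples correlated at medians of 0.18, 0.34, 0.47 and 0.44 for replicates 1 to 4, and as low as -0.07, 0.32, 0.35 and 0.05. The replicate number also fixes the dye, with a median correlation of 0.40 between samples of the same dye in other groups. Whether the numbers pair the samples therefore cannot be told apart from dye, and the main fit took no pairing. With the replicate number as a block the counts were 11, 15, 0, 7, 0, 26 and 7, with an overlap of 10 and 16 lists, all within 1.5 times, but the calls of miR-503* and miR-467a* in T1R1 and miR-883b-5p in T2R1 were lost. Signal over background limits these arrays, as 208 of 1023 mouse probes were above background in at least 4 samples.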

Other observations

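No test in this part was chosen in advance, and the values below were looked at only after the comparisons had been made.

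The small nuclear RNA probes, spotted as references and in none of the lists tested, lay above control in all 3 exposed groups. The spliceosomal RNA probe RNU1 stood at 0.23, 0.37 and 0.25 from control in T1R1, T2R1 and T3R1 on the log2 scale, RNU5 at 0.17, 0.33 and 0.33, RNU6-1 at 0.24, 0.38 and 0.16, and the probe for RNU6-1 and RNU6-2 at 0.16, 0.20 and 0.20. The U6B probe stood at 0.01, 0.02 and 0.09, and the ribosomal 5S_rRNA probe at 0.03, 0.57 and 0.38. Small nucleolar RNAs went both ways, with SNORD3@ at 0.19, 0.14 and 0.12, SNORD38B at 0.17, 0.14 and 0.06 and SNORD2 at 0.14, 0.20 and 0.05, and with SNORD48 at -0.06, -0.09 and -0.05 and SNORD65 at -0.02, -0.09 and -0.16. These differences were not tested, and no explanation is offered for them.

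By class of probe, the human virus probes, which have no target in these hearts, gave 0, 2 and 1 calls of 143 in T1R1, T2R1 and T3R1 against control, and the spike-in and landing-light probes 1, 2 and 0 of 63. As shares these were 0%, 1.40% and 0.70%, and 1.59%, 3.17% and 0%, where mouse probes gave 1.18%, 1.17% and 0%. For T3R1 against T1R1 the spike-in and landing-light class gave 4 calls of 63, 6.35%, where mouse probes gave 2.54%.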
